A study of Homo sapiens and Caenorhabditis elegans with 19 samples.

How the data were processed

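RNA-seq libraries of HEK293T cells with a mitochondrial matrix PRADA construct were used. Per the labels' protocols, cells took up s4U at 100 µM for 5 h, then alkyne phenol at 0.5 mM, and labelling was started with 10 mM D-amino acid for 30 min, while cells without D-amino acid were the unlabelled control. The names of the AP+DF and BP+DF columns of the 4SU table carry a suffix 20 that no label explains, so it is not known whether this dose applies to those libraries. These protocols describe s4U only, so no dose is given for 6SG, and the abbreviations AP, BP and DF are used as the titles give them. RNA was depleted of ribosomal RNA before library preparation, per the labels' protocols.

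The deposited values are raw fragment counts per gene, not normalized, per the file headers. Paired-end fragments were counted over exons and summed by gene with featureCounts 1.6.4 on GENCODE release 44, with no strand option and no multi-mapping option, per the file headers. Reads were aligned with STAR 2.7.9a to GRCh38, and DESeq2 1.42.0 is also named, per the submitters' processing notes. A deposited table of counts by assignment status gave 24751945 (AP+DF), 26947158 (AP), 41794061 (BP+DF), 22121489 (BP+H2O2) and 31562087 (BP) fragments. The assigned share was 37.2%, 40.2%, 45.8%, 50.2% and 48.9% in that order, and the unmapped share was 19.4%, 19.7%, 17.2%, 15.9% and 8.84%.

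Both tables held 62700 genes, and all 62700 took a symbol from the row annotation. GENCODE release 29 gave a biotype for 58207 of them, and 37 lay on the mitochondrial chromosome. A set of 404 pseudogenes was treated as nuclear copies of mitochondrial genes. Of 19 samples, 9 were used. Another 12 columns of per-sample values were not used here: 6 of the xenograft and 4 of the worm table carry only a date and a running number that no label holds, and 2 further 6SG columns end in I where the 4 used end in E, an ending that no label explains. The xenograft and worm samples were not analysed here. Column names assigned the 6SG libraries: names with both AP and DF were taken as labelled and names with AP alone as unlabelled.

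The 6SG libraries were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr, quasi-likelihood F tests (two-sided) and Benjamini-Hochberg adjustment over 18112 genes at a threshold of 0.05. The TMM factors, which enter the fold changes but not the printed CPM, were 0.939 and 0.937 (labelled) and 1.01 and 1.13 (unlabelled), and the common biological coefficient of variation was 0.176. Replicates within a group differed by more than sampling noise, with a chi-square per degree of freedom of 3.88 over 21014 genes (labelled) and 15.5 over 21581 genes (unlabelled). The script was tested on simulated data with 18112 genes. It recovered 63% of 100 genes changed 2-fold (median estimated log2 size 1.04) and 92% of 100 changed 4-fold (1.95), with 0 false among 155 calls. Only genes with a mean of 5 CPM or more were changed in that simulation. It gave both groups the same spread at a given expression, while the real groups differed. Its 0 false calls therefore do not cover unequal spread between groups.

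Gene lists were fixed before the data were examined, as were the tests and most alternatives. Of them 20 had 5 or more tested genes and entered limma 3.58.1's camera test on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01. The mitochondrial rRNA list with 2 tested genes and the erythroid list with 1 (ALAS2, log2 fold change 0.87, adjusted p 0.75) were not tested. Estimated correlations and limma's fry test were alternatives.

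The share of assigned fragments on mitochondrial genes was computed per library, with Wilson 95% intervals for single libraries and an exact permutation test for the 6SG groups. For the 4SU libraries, log2 ratios of CPM used a pseudocount of 1 CPM, and genes needed 50 or more counts in both libraries together. The median of each list was ranked among 10000 random lists of the same size, matched on mean expression in 20 bins. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used, and blastn 2.17.0 for sequence matches.

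Named genes followed a rule. It takes the mitochondrial mRNAs and rRNAs, the 10 largest increases and 10 largest decreases past the test with a mean of 5 CPM or more and no overlap between groups, and of each list up to 4 members with the lowest adjusted p and 2 with the highest CPM. For each 4SU ratio it takes the 5 largest and 5 smallest values. The exceptions, chosen after their values were seen, are HMGN5, TAF15, HNRNPA3 and HNRNPH3 and single 4SU values given for genes that another part of the rule names. Alternatives for scaling, count filter, tool, fold threshold and single libraries were run. The AP library as control for BP libraries and the comparison of BP+DF with AP+DF were added after the data were seen.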

Results

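The series measured RNA captured by proximity labelling from HEK293T cells, a human embryonic kidney line, that stably expressed a V5-tagged MITO-PRADA construct sent to the mitochondrial matrix. Fragments were counted per gene in 9 libraries of cultured cells out of 19 samples. In the 6SG design, 2 libraries came from labelled and 2 from unlabelled cells. In the 4SU design, each of 5 conditions had 1 library: AP, AP+DF, BP, BP+DF and BP+H2O2. The 6SG libraries held 7870255 and 8730234 assigned fragments with label and 9268443 and 8901923 without. The 4SU libraries held 10821938 (AP), 9204471 (AP+DF), 15430381 (BP), 19146349 (BP+DF) and 11111330 (BP+H2O2) assigned fragments. Titles call the 6SG libraries biological replicates. The p-values below for single genes, for the permutation test and for fry rest on these particular libraries. Those of the camera test with the preset correlation compare the genes of a list with other genes. They use genes as the units and do not measure replication between libraries. Intervals around a single library's share cover counting error only.

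The first question was how much of the captured RNA came from the mitochondrial chromosome. In the 6SG design that share was 22.5% ± 0.109 (SD, n = 2) in labelled cells and 6.54% ± 0.371 (SD, n = 2) in unlabelled cells, a ratio of 3.44 and a difference of 16.0 percentage points. Both labelled libraries lay above both unlabelled ones, and the gap was many times the spread between replicates. A two-sided exact permutation test of 2 against 2 libraries gave p = 0.33, which is the smallest p that this design allows. The 13 mitochondrial mRNAs, which encode subunits of the respiratory chain and the ATP synthase, held 21.9% ± 0.152 of the labelled and 6.39% ± 0.370 of the unlabelled fragments (SD, n = 2). Transfer RNA genes held 0.468% ± 0.0774 and 0.0877% ± 0.0154, a ratio of 5.33. Most of this share lay on MT-TC, with 3326 CPM (counts scaled to the library total) in labelled and 524 in unlabelled cells. MT-TN followed with 859 and 173 CPM. Gene by gene, the median log2 fold change was 1.92 for 19 tested tRNA genes and 1.96 for the 13 mRNAs. The ratio of 5.33 therefore does not show that tRNA genes in general rose more than mRNAs. The 2 mitochondrial ribosomal RNAs held 0.0879% ± 0.0344 and 0.0630% ± 0.0151, which is within the spread between replicates. Ribosomal RNA had been depleted before library preparation, so these shares cannot show whether the label enriches mitochondrial rRNA.

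**Figure D1:**
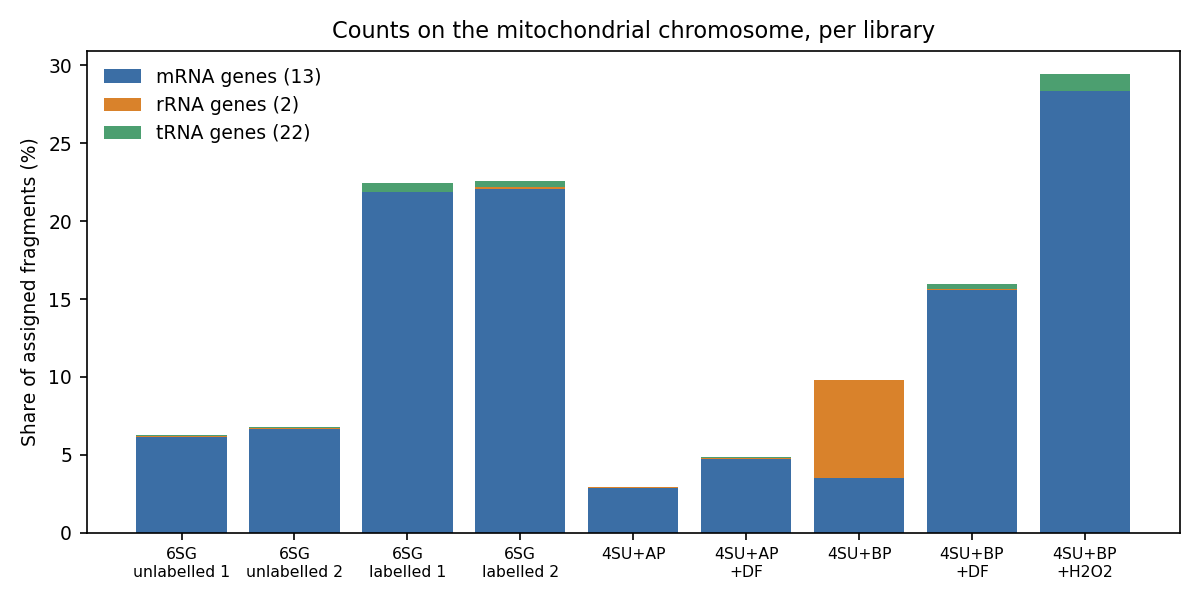
Bars show, for each of the 9 libraries, the percent of assigned fragments on mitochondrial mRNA, rRNA and tRNA genes (stacked); 1 bar is 1 library, with no error bars. The labelled 6SG libraries reach 22.5% on average against 6.54% without label, and the 4SU+BP library carries 6.31% on the rRNA genes.

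The next question was which single RNAs the label enriched. In edgeR's quasi-likelihood test of 2 labelled against 2 unlabelled 6SG libraries, 41 of 18112 genes passed a Benjamini-Hochberg adjusted p of 0.05, 37 of them higher and 4 lower with label. Of the 37, 20 lay on the mitochondrial chromosome, 12 were nuclear copies of mitochondrial genes and 5 were other nuclear genes. MT-CO1, the core subunit of cytochrome c oxidase and the most abundant of them (ENSG00000198804.2, GRCh38 chromosome M, 5904 to 7445), rose from 26240 ± 1741 to 88246 ± 877 CPM (SD, n = 2 each), where CPM scales a count to the library total. Its log2 fold change was 1.94 ± 0.25 (SE), with an adjusted p of 0.00029. Here and below, the SE of a log2 fold change is its absolute value divided by the square root of edgeR's F statistic. It is not a separate estimate from the spread of the libraries. MT-CO1 lost the call in 1 of 11 alternative settings, as did MT-ND2. MT-ND1, a subunit of complex I (ENSG00000198888.2, 3307 to 4262), rose from 1433 ± 74.96 to 7091 ± 246 CPM, a log2 fold change of 2.49 ± 0.22 with an adjusted p of 2.4e-06. Library-size scaling alone gave 35 higher and 21 lower genes in place of 37 and 4, and it shifted the median log2 fold change of all genes to -0.20.

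Of the 13 mitochondrial mRNAs, 12 rose with label among all genes and 13 when adjusted over the list alone, with a median log2 fold change of 1.96. The largest changes after MT-ND1 were those of MT-ND6, the only mRNA on the light strand (2.23 ± 0.21), and MT-ND4 (2.18 ± 0.23). Counting used no strand, so reads of MT-ND6 cannot be told from those of RNA of the opposite strand. MT-CYB, the cytochrome b of complex III, rose by 2.00 ± 0.22 and MT-ATP8, an ATP synthase subunit, by 2.03 ± 0.22. MT-ND3, another complex I subunit, had the smallest value, 0.69 ± 0.20 with an adjusted p of 0.31, and did not pass among all genes. The ribosomal RNAs MT-RNR1 (1.03 ± 0.24, adjusted p 0.13) and MT-RNR2 (-0.33 ± 0.33, adjusted p 0.84) did not pass either. After depletion of ribosomal RNA, these values do not tell whether the label enriches them. Without 1 library, MT-RNR1 ran from 0.66 (labelled library 2 left out) to 1.41 (unlabelled library 1), and MT-RNR2 changed sign, between -1.32 and 0.25. MT-RNR1 and MT-ND3 passed without either unlabelled library, MT-RNR1 also with no count filter and with a 10 CPM filter, and MT-ND3 also in DESeq2. In limma's camera test with the preset correlation, the mRNA list lay above the other genes (adjusted p = 3.8e-25). The adjusted p was 0.458 with an estimated correlation, so that call was lost. In limma's fry test, which asks whether a list moves at all and compares it with no other genes, the adjusted p was 0.0126.

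Of 19 mitochondrial tRNA genes tested, 8 rose among all genes and 16 when adjusted over the list alone. MT-TC, the cysteine tRNA gene (chromosome M, 5761 to 5826), rose from 524 ± 92.9 to 3326 ± 560 CPM (SD, n = 2), a log2 fold change of 2.86 ± 0.22. MT-TN, for asparagine, rose by 2.51 ± 0.21, MT-TW, for tryptophan, by 2.51 ± 0.35 and MT-TK, for lysine, by 3.22 ± 0.39. Without unlabelled library 2 the MT-TK value was 4.10, and without unlabelled library 1 it was 2.72. The list's median was 1.92 and its camera adjusted p 1.8e-21, against an adjusted p = 0.517 with an estimated correlation. Counting used no strand, so reads of a tRNA gene cannot be told from those of a precursor RNA of the opposite strand.

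**Figure D2:**
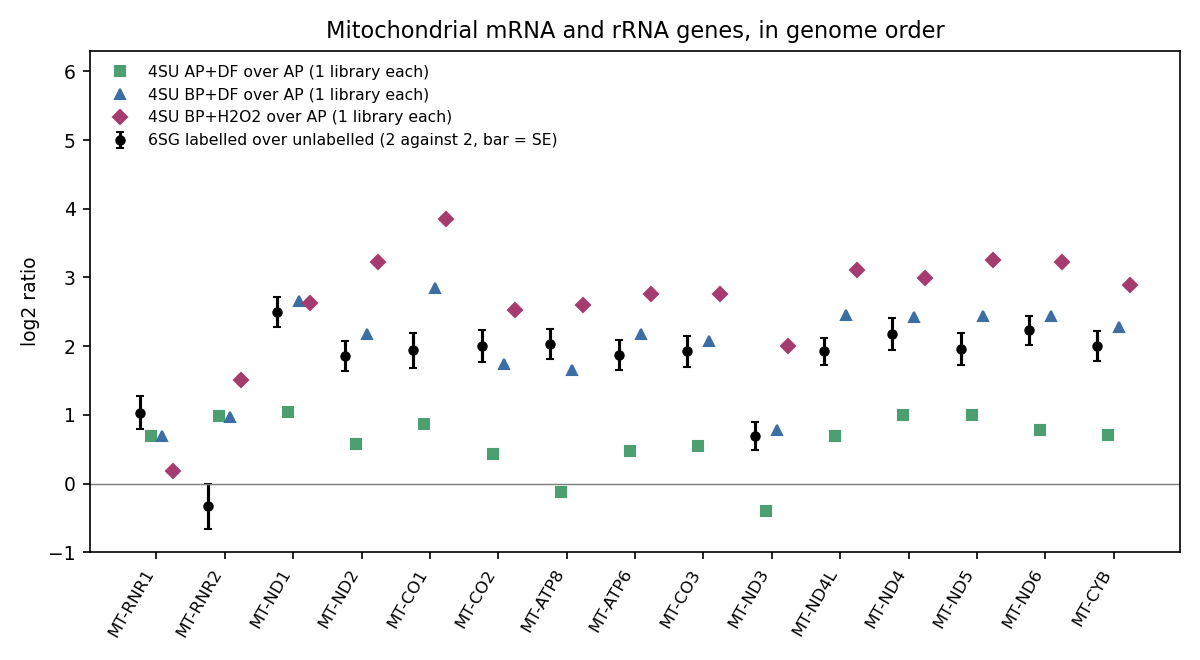
Points give log2 ratios (vertical axis) of the 13 mitochondrial mRNA and 2 rRNA genes (horizontal axis, genome order): black, 6SG labelled over unlabelled with SE (n = 2 each); colours, 4SU AP+DF, BP+DF and BP+H2O2 each over the AP library, 1 library each and no error bars. The AP library stands in as control for BP+DF and BP+H2O2 because the BP library differed in rRNA, a choice made after the values were seen. Those ratios change the compound together with the labelling condition, so they are not label over control alone. BP+DF over AP+DF had an mRNA median of 1.61.

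Nuclear copies of mitochondrial genes followed the same direction, with 12 of 37 tested higher and a median log2 fold change of 1.83. MTND1P23 (chromosome 1, 629062 to 629433) rose by 3.42 ± 0.30, MTND6P4 by 3.03 ± 0.29 and MTCO3P12 by 2.85 ± 0.21. These copies share sequence with the mitochondrial genes, so their reads cannot be placed with certainty. The named copies MTND4P12 (2.84 ± 0.19), MTCO2P12 (2.71 ± 0.21) and MTND5P11 (2.51 ± 0.25) rose as well.

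Among the 18041 other nuclear genes, 5 rose and 4 fell with 6SG label, and of these HMGN5, TAF15, HNRNPA3 and HNRNPH3 were named after their values were seen. MALAT1, a long noncoding RNA of nuclear speckles (chromosome 11, 65497640 to 65508073), rose from 22.8 ± 4.00 to 55.6 ± 10.7 CPM (SD, n = 2), a log2 fold change of 1.48 ± 0.20 with an adjusted p of 0.00063. HMGN5, a nucleosome-binding protein, rose by 1.26 ± 0.20. Genes of 3 RNA-binding proteins rose, TAF15 by 1.14 ± 0.18, HNRNPA3 by 1.12 ± 0.18 and HNRNPH3 by 0.90 ± 0.17. FOS, an immediate early transcription factor, fell by 1.49 ± 0.28 from 44.2 ± 25.5 to 13.6 ± 0.227 CPM (SD, n = 2, adjusted p 0.026). Without unlabelled library 2 the FOS value was -0.84, and without unlabelled library 1 it was -1.90. SCARNA5, a small RNA of Cajal bodies, fell by 1.58 ± 0.27 and SNORA53, a small nucleolar RNA, by 2.89 ± 0.57. The SNORA53 value was -5.06 without labelled library 2 and -2.097, with the call lost, without labelled library 1. POGLUT2, a protein glucosyltransferase, fell by 1.15 ± 0.23 (adjusted p 0.045) and lost the call in 4 of 11 alternative settings. Against a 2-fold threshold in edgeR (glmTreat) all 9 lost the call, while 16 of the 20 called genes on the mitochondrial chromosome kept it. Each of the 9 except MALAT1 and FOS also lost it in at least 1 fit without 1 labelled library.

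**Figure D3:**
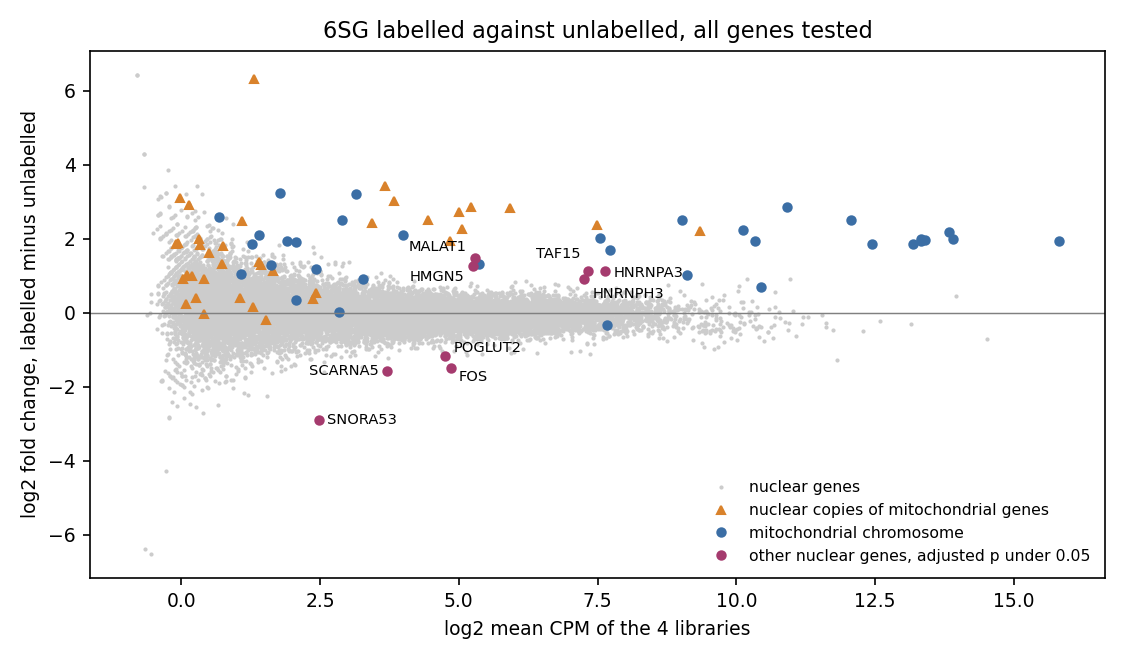
Each point is 1 of 18112 genes, with log2 mean CPM of the 4 6SG libraries on the horizontal axis and log2 fold change, labelled minus unlabelled, on the vertical axis. The mitochondrial genes and their nuclear copies lie mostly above 0 (medians 1.93 and 1.83), and the 9 named nuclear genes are those with an adjusted p under 0.05.

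Several nuclear-encoded groups fixed in advance lay below the other genes in limma's camera test with the preset correlation. Over all 18112 genes, 1625 had an unadjusted edgeR p under 0.05 in either direction. Counts of list members at that level, here and below, are to be read against this background. Cytosolic ribosomal protein genes had a median log2 fold change of -0.40 (adjusted p = 9.4e-09, but adjusted p = 0.884 with an estimated correlation), with RPL9 at -0.99 ± 0.21 and RPS3A at -0.92 ± 0.22. In edgeR none of its 76 genes passed among all genes, 11 were lower when adjusted over the list alone, 32 were lower at an unadjusted p of 0.05, and DESeq2 called 4 lower. Replication-dependent histone genes had a median of -0.72 (adjusted p = 6.6e-08, but adjusted p = 0.884 with an estimated correlation), with H2AC20 at -1.05 ± 0.24. In edgeR none of the 41 histone genes passed among all genes, 21 were lower adjusted over the list alone, 24 were lower at an unadjusted p of 0.05, and DESeq2 called 0. Small noncoding RNAs had a median of -0.69 (adjusted p = 0.00017, but adjusted p = 0.884 with an estimated correlation), and of 14 tested SCARNA5 fell among all genes and 6 fell adjusted over the list alone. RMRP, the RNA of RNase MRP, stood at -1.27 ± 0.28 with an adjusted p of 0.11. Immediate early genes had a median of -0.45 (adjusted p = 3.9e-05, but adjusted p = 0.884 with an estimated correlation), with FOS lower among all genes and 4 of 21 lower adjusted over the list alone. EGR1, a zinc finger transcription factor, stood at -1.12 ± 0.28 with an adjusted p of 0.21.

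Nuclear genes of the respiratory chain had a median of -0.29 (camera adjusted p = 0.00017, but adjusted p = 0.884 with an estimated correlation), with ATP5F1C, an ATP synthase subunit, at -0.82 ± 0.21. In edgeR none of these 77 genes passed among all genes or adjusted over the list alone, 31 were lower and 5 higher at an unadjusted p of 0.05, and DESeq2 called 0. Mitochondrial ribosomal protein genes had a median of -0.23 (adjusted p = 4.1e-05, but adjusted p = 0.884 with an estimated correlation), with MRPL4 at -0.77 ± 0.20. In edgeR none of the 76 passed either way, 14 were lower at an unadjusted p of 0.05, and DESeq2 called 0. All 6 lower lists thus lost the call. In fry, which tests each list against no change and not against other genes, their adjusted p was 0.770. Without unlabelled library 1, only the lists of mitochondrial mRNAs, tRNAs and immediate early genes passed, and the respiratory chain list pointed up. In another fit without 1 library the immediate early list did not pass.

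The other lists did not pass the camera test. Counts of their members at an unadjusted p of 0.05 are again to be read against 1625 of all 18112 genes. Endoplasmic reticulum and secretory genes had a median of -0.11 and an adjusted p of 0.060, with 1 higher (SEC63, 0.65 ± 0.17) and 4 lower adjusted over the list alone; library-size scaling gave an adjusted p of 0.0069 (0.0013 to 0.884 over all settings). Nuclear-retained long noncoding RNAs had a median of 0.12 (adjusted p 0.0999), which became -0.07 under library-size scaling, and MALAT1 alone rose. Glycolytic enzymes had a median of -0.14 (adjusted p 0.599), with HK1 at 0.56 ± 0.17 among 2 higher adjusted over the list alone. Matrix enzymes and chaperones (median -0.09, adjusted p 0.599), hypoxia genes (-0.11, 0.599), integrated stress response genes (-0.10, 0.151), NRF2 targets (-0.08, 0.224) and heat shock genes (0.01, 0.722) did not pass. In edgeR none of the members of these 5 lists passed among all genes or adjusted over the list alone, 1 matrix gene was higher, 3 matrix, 2 hypoxia, 4 stress response, 1 NRF2 and 2 heat shock genes were lower at an unadjusted p of 0.05, and DESeq2 called 0. Marker lists of other cell types did not pass: leukocyte (0.16, adjusted p 0.401), endothelium (-0.10, 0.722), stroma (-0.03 with a mean of 0.13 and a test direction above 0, 0.833) and muscle and fat (0.28, 0.870). The heat shock list had a mean of -0.04 and a test direction below 0, opposite to its median. In edgeR none of the members of these 4 marker lists passed among all genes or adjusted over the list alone, 1 stroma gene was higher and 1 lower at an unadjusted p of 0.05, as was 1 endothelium gene lower, and DESeq2 called 0.

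The unlabelled pair set much of the 6SG count. Between the unlabelled libraries the chi-square per degree of freedom was 15.5, against 3.88 between the labelled ones. Without unlabelled library 1 the test called 392 genes, and without unlabelled library 2 it called 1949, with the lone library assumed to vary like the labelled pair. Without labelled library 1, 2 genes in place of 4 were lower.

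The 4SU libraries asked the same question with other labelling conditions. Each condition had 1 library without replicates, and no p-value was computed for single ratios or across the conditions. The AP+DF library had 4.88% of its fragments on the mitochondrial chromosome (Wilson 95% interval 4.87 to 4.89), against 2.95% (2.94 to 2.96) in the AP library, a ratio of 1.66. The median log2 ratio of the 13 mitochondrial mRNAs was 0.69, with 11 above and 2 below 0. MT-ND1 stood at 1.03 and MT-CO1 at 0.86, while MT-ND3 stood at -0.40 and MT-ATP8 at -0.13. The 15 mitochondrial tRNA genes with enough counts were all above 0, with a median of 1.31, and MT-TD, for aspartate, had 2.21. Among 15136 nuclear genes, 13 were over 2-fold higher and none was over 2-fold lower, a description of 1 library pair without a test. The medians of nuclear-retained long noncoding RNAs (0.15) and small noncoding RNAs (0.26) were above 0, and those of histone (-0.15), cytosolic ribosomal protein (-0.14) and nuclear respiratory chain genes (-0.12) were below 0, under every scaling tried. Among 10000 random lists of matched expression, the nuclear-retained list stood at percentile 100 and the small noncoding RNA list at 99.995. The histone, cytosolic ribosomal protein and respiratory chain lists stood at percentile 0. The small noncoding RNA list pointed the other way with 6SG label, with a median of -0.69.

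With BP, the BP+DF library had 15.9% of fragments on the mitochondrial chromosome (15.92 to 15.95) and the BP+H2O2 library 29.5% (29.44 to 29.49), against 9.82% (9.80 to 9.83) in the BP library. In the BP library, however, the 2 mitochondrial rRNA genes alone held 6.31% of fragments, with MT-RNR1 at 40894 CPM and MT-RNR2 at 22158 CPM, against 203 and 58.6 CPM in the AP library. The share ratio over BP was 1.62 for BP+DF and 3.00 for BP+H2O2, and without the rRNA genes it was 4.24 and 7.85. MT-CO1 counted 8910 CPM in BP, 75923 in BP+DF and 152024 in BP+H2O2. The median log2 ratio of the 13 mitochondrial mRNAs over BP was 1.76 for BP+DF and 2.34 for BP+H2O2, with all 13 above 0 in both. The median of the 19 tRNA genes was 2.46 and 3.08.

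Most of the 2-fold differences in nuclear genes of the BP libraries went with the choice of control. Over BP, 145 of 17043 nuclear genes were over 2-fold higher and 716 over 2-fold lower in BP+DF, and 77 of 15595 were higher and 1394 lower in BP+H2O2. With the AP library as control, 8 of 16204 were higher and 19 lower in BP+DF. In BP+H2O2, 14 of 14665 were higher and 307 lower. That control was chosen after the values were seen and differs in compound too. The median log2 ratio of nuclear genes over BP was -0.08 and -0.34, so values in BP+H2O2 are to be read against that shift. Over AP it was -0.21 and -0.48, while the median of all genes with TMM factors was 0.02 and -0.00405, so the 307 lower genes are to be read against that shift as well. PIGC, an enzyme of glycosylphosphatidylinositol anchor synthesis (chromosome 1, 172370189 to 172444086, overlapped by 2 genes on the other strand), had the largest nuclear ratio over BP, with 16.14 CPM in BP, 25.3 in AP, 114 in BP+DF and 334 in BP+H2O2. HSPA1B, an inducible heat shock protein, had 111.7 CPM in BP, 590 in AP, 526 in BP+DF and 442 in BP+H2O2. NPC1L1, an intestinal cholesterol transporter, had 28.3 CPM in BP, 2.59 in AP, 1.04 in BP+DF and 0.900 in BP+H2O2. Over BP, histone genes had medians of -0.78 (BP+DF) and -1.15 (BP+H2O2), and cytosolic ribosomal protein genes of -0.49 and -0.65. Of the marker lists of other cell types, 3 lists of 3 or 4 genes lay low as well: leukocyte -1.32 and -1.82, muscle and fat -1.02 and -1.71, endothelium -0.90 and -1.01. The stroma list of 7 genes stood at -0.29 and -0.61, at percentiles 14.7 and 11.0 of matched random lists. Over AP, the histone medians were -0.13 and -0.59 and the ribosomal protein medians -0.23 and -0.39. With TMM factors over AP, histone genes stood at 0.10 in BP+DF and -0.11 in BP+H2O2 and ribosomal protein genes at 0.02 and 0.12, so 3 of these 4 directions turned. The BP library itself had histone genes at 0.67 and ribosomal protein genes at 0.27 over AP. It also had leukocyte markers at 1.30 (4 of 4 above 0), muscle and fat markers at 0.64 and ALAS2, the only erythroid marker with enough counts, at 1.59, but endothelium markers at 0.29 and stroma markers at 0.09 (4 of 7 above 0).

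Both oxidation conditions with BP were then compared directly. The mitochondrial share was 1.85 times as high with H2O2 as with DF, and 12 of 13 mitochondrial mRNAs had a higher value, with a median log2 ratio of 0.78. MT-CO1 stood at 1.00, while MT-ND1 stood at -0.03. The largest ratios belonged to 3 tRNA genes next to each other on the light strand, MT-TC (2.13), MT-TN (2.08) and MT-TY (1.66). Of 19 tRNA genes 13 were above 0 and 6 below, with a median of 0.60. With TMM factors the tRNA median was 0.85, so the sign of values just below 0, such as that of MT-ND1, depends on the scaling. MT-TC counted 7145 CPM with H2O2 and 1632 CPM with DF. Of 15688 nuclear genes, 9 were over 2-fold higher and 24 over 2-fold lower, and the median of nuclear genes was -0.26.

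**Figure D4:**
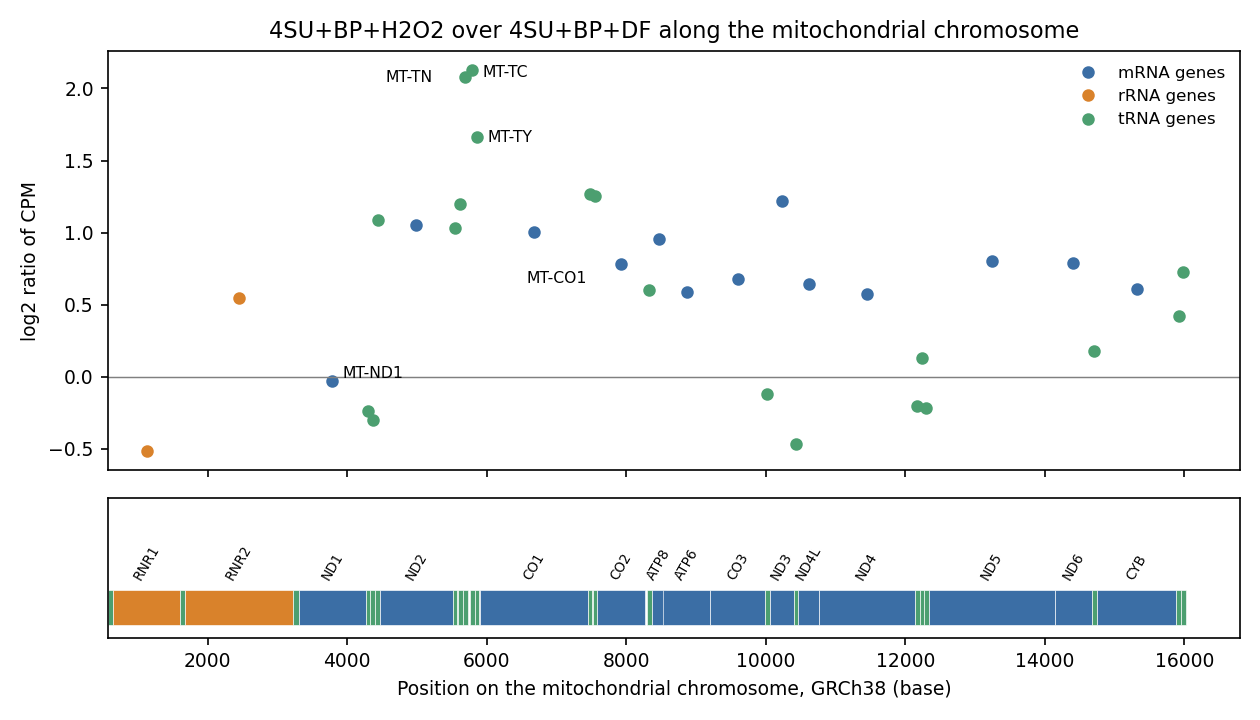
Upper part, log2 ratio of CPM in BP+H2O2 over BP+DF (vertical axis, 1 library each) for each gene of the mitochondrial chromosome at its GRCh38 position in bases (horizontal axis); lower part, the genes to scale. Colours mark mRNA, rRNA and tRNA genes, and MT-TC, MT-TN and MT-TY reach 2.13, 2.08 and 1.66.

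The compounds AP and BP were compared at the same DF condition, with 1 library each and no test, in a comparison added after the files were seen. The mitochondrial share was 15.9% with BP+DF and 4.88% with AP+DF, a ratio of 3.27. All 13 mitochondrial mRNAs were higher with BP+DF, by a median log2 ratio of 1.61, and 18 of 19 tRNA genes were higher, by a median of 1.49. MT-CO1 had 75923 CPM with BP+DF and 19239 CPM with AP+DF. The ribosomal RNAs were alike in CPM, at 330 and 329 for MT-RNR1 and 115 and 117 for MT-RNR2. Their median log2 ratio was -0.01, and 0.26 with TMM factors. Ribosomal RNA had been depleted, so these values do not tell whether labelling enriches them. Among 16079 nuclear genes, 2 were over 2-fold higher with BP+DF and 47 over 2-fold lower. The median of nuclear genes was -0.20, and that of all genes with TMM factors 0.06, so these counts are to be read against that shift. PIGC had 114 CPM with BP+DF and 32.4 CPM with AP+DF, while SNORA53 had 3.34 and 11.6 CPM.

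Nuclear genes were also compared between the designs. Across 14703 nuclear genes, the 6SG log2 fold changes and the AP+DF over AP log2 ratios had a Pearson r of 0.24 and a Spearman rho of 0.29. Across the 7527 genes with 20 CPM or more, these were 0.44 and 0.46. Both are correlations across genes, which are not independent replicates, and the designs share no library. All 5 nuclear genes that rose with 6SG label were higher in AP+DF than in AP, with a median log2 ratio of 0.46. Of the 4 that fell, SCARNA5 (0.54), FOS (0.35) and SNORA53 (0.56) went the other way and were higher in AP+DF, and only POGLUT2 (-0.24) was lower.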

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

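The tests on the BP library, on PIGC and on chance in the 6SG libraries were chosen only after those results were seen, and the test on chance replaced an earlier one, already run, in which the median of the 5 genes in AP+DF over AP stood at percentile 100 among matched random lists, with the same verdict.

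Some genes pointed one way under one labelling condition and the other way under another, and none of these differences was tested; each 4SU value rests on 1 library per condition. MT-ND3, which stood at 0.69 with 6SG label, had a log2 ratio of -0.40 in AP+DF over AP and 0.87 in BP+DF over BP. MT-ATP8 rose with 6SG label but had -0.13 in AP+DF over AP and 1.37 in BP+DF over BP. MT-RNR1 had -6.95 and MT-RNR2 -7.57 in BP+DF over BP, while both were above 0 in AP+DF over AP. Those negative values came from the BP library, since the same BP+DF library had 0.70 and 0.96 over AP. SCARNA5 fell with 6SG label but had 0.54 in AP+DF over AP and -0.73 in BP+DF over BP. SNORA53 fell as well, with 0.56 and -0.72 in those ratios. FOS also fell, with 0.35 and -0.17.

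The BP library carried far more mitochondrial rRNA than any other, and no biological explanation was tested. Its rRNA share was 241 times that of the AP library, while its mitochondrial mRNA share was 1.21 times, which does not match more mitochondrial RNA of every kind. Less complete removal of ribosomal RNA could not be judged: genes of nuclear rRNA summed to 43.6 CPM in BP and 38.4 to 65.8 CPM in the others, but the mature cytosolic rRNA genes hold no uniquely assigned fragment. Against that, 2 microRNA genes of the ribosomal DNA region were highest in BP and go with that explanation, though neither is mature rRNA. MIR3648-1 had 25.8 CPM against 1.08 to 4.86 in the others, and MIR3648-2 had 3.24 against 0.45 to 1.63. The multi-mapping share of fragments was 8.31% in BP and 5.86% to 7.33% in the others, a small difference that does not settle it. Whatever the source, ratios over BP carry this difference of the control library.

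The nuclear transcripts MALAT1, HMGN5, TAF15, HNRNPA3 and HNRNPH3 rose with 6SG label, 5 in all. The trends with GC content and transcript length over nuclear genes did not account for it, as both were weak (Spearman -0.11 and 0.04). The median log2 fold change of the 5 was 1.16 after both trends were removed and 1.14 before. These genes were chosen by the same fold changes, so removing weak trends could hardly have lowered them. Reads shared with mitochondrial genes did not account for it either, since the longest stretch matching a mitochondrial transcript was 20 bases. All 5 lay above both controls in all 3 labelled 4SU libraries, as did 3.27% of nuclear genes, while 20.7% lay below both. Interchangeable libraries would give 10% each way, so the groups differed throughout and 10% is no yardstick. Set against the 3.27%, which was not matched on expression, this speaks against chance in the 4 6SG libraries for these 5 genes. They may not be independent, and their high values in AP+DF over AP were already known when this criterion was chosen. The comparison does not cover the genes that fell: SCARNA5 (0.54), FOS (0.35) and SNORA53 (0.56) were higher in AP+DF than in AP. These RNAs may be captured with the label, but where they were in the cell was not tested, and all except HMGN5 overlap genes on the other strand, which unstranded counts cannot separate.

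PIGC had 16.14 CPM in BP, 25.3 in AP, 32.4 in AP+DF, 114 in BP+DF and 334 in BP+H2O2. Reads shared with mitochondrial transcripts are unlikely, since the longest match was 17 bases. A low BP control does not account for all of it, since the smaller log2 ratio against AP was 2.12. The AP library differs in compound as well. With 6SG label PIGC stood at 0.71 ± 0.27 (adjusted p 0.47), below the mitochondrial mRNA median of 1.96, but MT-ND3, itself a mitochondrial mRNA, stood at 0.69 ± 0.20. Capture of PIGC along with those mRNAs therefore stays open, and PIGC was higher in each labelled 4SU library than in its own control. Its span overlaps 2 genes on the other strand, DNM3 and C1orf105, which unstranded counts cannot separate, and no biological explanation was tested.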

How the results depend on the processing

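The count of 41 genes (37 higher, 4 lower) moved with the setting, and more genes were higher than lower in every setting except without unlabelled replicate 2. Library-size scaling gave 21 lower genes. No count filter gave 105 (58 higher, 47 lower), a 10 CPM filter 68 (18 lower), glmTreat 0 lower (139 genes at an unadjusted p of 0.05) and DESeq2 65 (14 lower). Leaving out 1 library gave 34 to 1949 genes, 32 to 677 higher and 2 to 1272 lower. List calls numbered 8, and 0 with an estimated correlation, 1 (mitochondrial mRNAs) in fry and 3 to 13 without 1 library; fry compares a list with no change and not with other genes. Without unlabelled replicate 1 the nuclear respiratory chain list turned upward; its signed -log10 p ran from -10.86 to 0.22 without 1 library. Among single named genes 341 results stayed called or uncalled as before, 8 gained and 24 lost the call. The share difference of 16.0 points became 17.0 with coding genes as total and 15.7 to 16.23 without 1 library. For AP+DF over AP the share ratio became 1.67 with coding genes as total. For BP+DF over BP the mRNA median of 1.76 became 2.28 with AP as control, 1.87 with TMM and 1.86 without mitochondrial genes in the total, and the share ratio of 1.62 became 5.40 with AP, 1.61 with coding genes as total and 4.24 without rRNA. For BP+H2O2 over BP the median of 2.34 became 2.89, 2.697 and 2.69, and the share ratio of 3.00 became 9.99, 2.96 and 7.85, in the same order. For BP+H2O2 over BP+DF the median of 0.78 became 1.04 with TMM and 1.04 without mitochondrial genes, and the share ratio 1.83 with coding genes as total. For BP+DF over AP+DF the median of 1.61 became 1.88 with TMM and 1.78 without mitochondrial genes. The cause was not tested where the setting's own construction does not show it. AP as control and BP+DF over AP+DF were chosen after seeing the data. With AP as control for BP+DF or BP+H2O2, the compound changes together with the labelling condition. No paired analysis was possible because the 6SG columns carry no replicate numbers and the 4SU groups have 1 library each. Alternatives for the xenograft and worm samples were not run. How well changes in genes under 5 CPM are recovered was not simulated, and neither was a spread that differs between groups.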

Other observations

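Beyond the comparisons, the AP and BP control libraries differed from each other in nuclear genes. Of 16142 nuclear genes, 467 were over 2-fold higher and 330 over 2-fold lower in BP than in AP, with 1 library each and no test. HSPA1B, an inducible heat shock protein, counted 111.7 CPM in BP and 590 CPM in AP. HMOX1, the inducible heme oxygenase, counted 9.14 CPM in BP and 44.4 CPM in AP. NPC1L1 counted 28.3 and 2.59 CPM. MIR3648-1, a microRNA gene within the ribosomal DNA region, counted 25.8 and 2.31 CPM. The median log2 ratio of the 13 mitochondrial mRNAs in BP over AP was 0.43.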
